A study of Homo sapiens with 20 samples.

How the data were processed

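U2OS-GR cells, a human osteosarcoma line that expresses the glucocorticoid receptor, were compared as control cells and as 2 clones that overexpress Hes1. Per the labels, cells received 100 nM dexamethasone (DEX), a synthetic glucocorticoid, for 6 h or were left without it (VEH), and 500 ng of total RNA was labelled with Cy3 or Cy5. Each of the 20 Agilent arrays held 2 of these RNAs, and the array titles named both RNAs, their dyes and the replicate. The 5 comparisons were DEX against VEH in control cells, in clone 1 and in clone 2, and clone 1 and clone 2 each against control cells, all under VEH. Each comparison had 2 replicates, and each replicate was a pair of arrays with the dyes exchanged.

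Per the file headers, the scanner files give intensity as the mean signal and the median background of each spot in Cy3 (green) and Cy5 (red), extracted by the authors with Agilent Feature Extraction 8.5.1.1. The deposited log10 ratio of Cy5 over Cy3 was made by the authors from background-subtracted signals with spatial detrending and LOWESS dye normalisation. The deposited series table held the same log10 ratio as the scanner files, with a largest difference of 0 and a median of 0 on every array. That ratio differed from the ratio of the processed signals of both channels for 792 to 1692 of 43931 features per array, and all of these had a deposited ratio of 0.

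The log2 ratios reported here were computed from the intensities with limma 3.58.1, the data.table package (1.17.8) and statmod 1.5.0 in R 4.3.3, after reading with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. Background was corrected with normexp and an offset of 50, and ratios were normalised within each array by loess with control spots and spots marked as outliers given no weight. Ratios were turned so that the numerator was DEX, or the clone, whichever dye it carried. Control spots (2256 per array) and outlier spots (6 to 539 per array) were left out, and spots of the same probe were averaged.

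The 41000 distinct probes were named by transcript accession (22769), by current symbol (2407), by a synonym held by a single gene (1170) or, failing these, by the name in the scanner file (14654). A table of human RefSeq genes served for these names only, and the scanner files give probe coordinates without a genome build. The names covered 31132 genes or transcripts, of which 7465 had more than 1 probe and were read from the probe that was brightest on average. A gene was tested when its signal was well above background in either channel on at least 4 of the 20 arrays, which left 30520, of which 17177 had a current symbol. For DEX in clone 2 and the differences that use it, 30485 genes had values.

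The arrays had median signals of 174 to 322 in Cy3 and 163 to 306 in Cy5, over median backgrounds of 52 to 61 and 51 to 54. Between 6 and 124 spots per array were saturated in Cy3 and between 16 and 192 in Cy5. The precision is limited by the number of arrays. Each pair of arrays with exchanged dyes was averaged to 1 value, and all 10 values entered a single limma fit with 5 residual degrees of freedom and 2.64 prior degrees of freedom. The median residual SD was 0.0742 and the median SE of a comparison was 0.0512 on the log2 scale. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences in DEX response were tested as contrasts of the fitted comparisons, and the response of the clones was also taken as the mean of both.

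Before the data were examined, 24 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and also with an estimated correlation and with limma's fry. The rule took genes with a symbol, past the threshold and of the same sign on every array of the comparison. It took the 10 largest changes each way for DEX in control cells and the 5 largest each way for each clone. For clones against control it took the 10 largest each way by the mean of both clones, past the threshold in both. For the difference in DEX response it took the 10 largest each way with the same sign in both clones. HES1 and NR3C1 were always named, and up to 4 members with the largest change were taken from each list described.

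The share of the control response kept in the clones was computed on genes chosen in 1 control replicate, with an absolute log2 ratio of at least 1 in both dye orientations, and measured in the other. It was the median clone ratio over the median control ratio, both signed in the control direction. On simulated data in which every changed gene kept 0, 30 or 100% of its response it returned 0.017, 29.9 and 99.96%. No gene was reversed in the simulated data, so that case was not tried. The fit was tested on simulated data with 30520 genes. For DEX in control cells it recovered 77.6% of changes of 0.58 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2, with 13 false calls (6.60% of calls). For clone 1 against control the figures were 85.1, 97.0 and 98.5%, with 10 false calls (5.08%). For the difference in DEX response they were 83.6, 92.5 and 100%, with 10 false calls (5.15%), and with no gene changed there were 0 calls.

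Alternatives covered background correction, normalisation, scaling, the choice of probe, the filter on dim probes, saturated spots, the handling of the dye pairs, the extent of the fit, the variance prior, both thresholds, and each replicate left out in turn. A fit within each scan date and array weights were added after seeing the data. Scan date could not be entered as a term, because all arrays of a comparison shared a single date.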

Results

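RNA of U2OS-GR osteosarcoma cells was measured on 20 arrays, each holding 2 RNAs in Cy3 and Cy5. The arrays formed 5 comparisons of 4 arrays, and each comparison had n = 2 replicates with the dyes exchanged. HES1 is a transcriptional repressor downstream of Notch, and both clones overexpress Hes1. Between 92.2% and 97.4% of spots were well above background in Cy3 and between 90.9% and 96.4% in Cy5, and the number of arrays limits the precision. Values are log2 ratios, given as the mean of the 2 replicates with their SD, and adjusted p-values are from limma over all genes tested. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which can be technical. Each gene taken by the naming rule for a single comparison had the same sign on all 4 of its arrays.

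DEX against VEH in control cells asked which transcripts the glucocorticoid changed within 6 h. RGS2, a regulator of G-protein signalling, rose by 4.56 (SD 0.023, n = 2, limma adjusted p = 4.7e-07) and ITGB2, the beta chain of leukocyte integrins, rose by 3.59 (SD 0.16, adjusted p = 2.4e-07). LPL, the lipase that frees fatty acids from lipoproteins, rose by 3.79 (SD 0.69), and the Notch ligand DLL1 rose by 3.49 (SD 0.91). AMIGO2, a cell adhesion protein, fell by 4.18 (SD 0.48, adjusted p = 1.5e-06), the transcription cofactor FHL2 fell by 4.08 (SD 0.23) and PMEPA1, an inhibitor of TGF-beta signalling, fell by 3.26 (SD 0.82). NR3C1, the glucocorticoid receptor itself, fell by 1.63 (SD 0.029, adjusted p = 1.7e-05). HES1 fell by 1.95 at its brightest probe (SD 0.093, adjusted p = 3.3e-04), fell by 1.51 at its most 5′ probe (adjusted p = 3.1e-05) and read -0.49 at its middle probe (adjusted p = 0.156). The middle probe was dim in these cells, with a DEX signal not well above background on 1 array.

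The rule also named FAM90A1 (5.19), TAMALIN (4.63), FLRT3 (3.88), KBTBD11 (3.39), ARC (3.09) and ATP4A (3.01) among the largest increases. Among the largest decreases were IRF2BP2 (-3.07), ADAMTS6 (-2.98), LRIG3 (-2.91), HMGA2 (-2.91), FRMD6 (-2.81), HSPA1A (-2.78) and KCNK1 (-2.77). FAM90A1 has close paralogs that its probes can also read. Another probe of ADAMTS6 read 0.02 (adjusted p = 0.858), and the weakest probes of IRF2BP2, HMGA2, FRMD6 and HSPA1A read -1.63, -0.26, -0.95 and -1.47. DEX changed 7284 of 30520 genes in control cells, 3438 higher and 3846 lower, and 656 of them by at least 2-fold (372 higher and 284 lower). The count was 3833 with median centring in place of loess and 3964 when only the 4 arrays of this comparison were fitted.

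Of 36 genes known to be induced by glucocorticoids, 18 rose in control cells, 5 fell and 13 did not pass (camera adjusted p = 9.9e-05, adjusted p = 0.389 with an estimated correlation), and adjusted over the list alone 20 rose and 5 fell. Beside RGS2, these included CEBPD, a transcription factor of the acute response, at 2.81 (SD 0.076), and the thiamine transporter SLC19A2 at 2.28 (SD 0.042). KLF15, a transcription factor of amino acid metabolism, rose by 2.58, but its other probe read 0.06. Small or opposite values, for genes chosen after their values were seen, were read in 3 other members. FKBP5, a chaperone that restrains the receptor, read 0.29, a call lost without control replicate 1 (0.19) and at its weakest probe (0.18), the phosphatase DUSP1 read 0.39, a call lost without replicate 1 (0.41) or 2 (0.37), and DDIT4, an inhibitor of mTOR signalling, fell by 0.76 (adjusted p = 3.2e-04).

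Of 15 heat shock genes, 11 fell, 0 rose and 4 did not pass in control cells (camera adjusted p = 4.2e-08, adjusted p = 0.389 with an estimated correlation), and adjusted over the list alone 13 fell. The chaperones HSPA1L, DNAJB1 and HSPH1 fell by 1.53 (SD 0.0095), 1.42 (SD 0.0037) and 1.28 (SD 0.16). Of 31 genes of G2 and mitosis, 20 fell, 0 rose and 11 did not pass (camera adjusted p = 3.4e-06, adjusted p = 0.548 with an estimated correlation), and adjusted over the list alone 21 fell. The ubiquitin-conjugating enzyme UBE2C fell by 0.90 (SD 0.031) and the spindle protein TPX2 fell by 0.58 (SD 0.029), while CDK1, the kinase that starts mitosis, read -0.64, a call lost without replicate 2 (-0.54).

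Of 34 immediate early genes, 14 fell, 3 rose and 17 did not pass in control cells (camera adjusted p = 1.8e-04, adjusted p = 0.594 with an estimated correlation), and adjusted over the list alone 15 fell and 3 rose. IER3, an early gene that limits cell death, fell by 2.41 (SD 0.017), the transcription factor EGR1 fell by 1.72 (SD 0.28) and KLF10, a factor induced by TGF-beta, fell by 1.64 (SD 0.27). Of 24 genes of the receptor machinery, 12 fell, 3 rose and 9 did not pass (camera adjusted p = 0.0032, adjusted p = 0.548 with an estimated correlation), and adjusted over the list alone 13 fell and 4 rose. Beside NR3C1, the mineralocorticoid receptor NR3C2 fell by 0.82 (SD 0.15), and HSD11B2, which inactivates cortisol, rose by 1.64 (SD 0.56). Without control replicate 2 the receptor list did not pass (camera adjusted p = 0.069).

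Cholesterol genes went both ways in control cells. Of 20, 10 fell, 4 rose and 6 did not pass (camera adjusted p = 0.036, adjusted p = 0.677 with an estimated correlation), and adjusted over the list alone 12 fell and 4 rose. SQLE, an oxygen-requiring enzyme of sterol synthesis, fell by 1.15 (SD 0.25), whereas NSDHL, a later enzyme of that pathway, rose by 1.57 (SD 0.0058). Of 12 metallothioneins, metal-binding proteins that glucocorticoids can induce, 3 fell, 0 rose and 9 did not pass (camera adjusted p = 0.025, adjusted p = 0.675 with an estimated correlation), and adjusted over the list alone 6 fell and 1 rose. Of 46 ribosomal protein genes, 7 rose, 0 fell and 39 did not pass (camera adjusted p = 0.0072, adjusted p = 0.548 with an estimated correlation), and adjusted over the list alone 6 rose. Without control replicate 2 the cholesterol (0.076), metallothionein (0.144) and ribosomal (0.069) calls were lost, and the metallothionein call also without clone 2 replicate 2 of DEX against VEH (0.0543). With saturated spots left out the metallothionein (0.835) and ribosomal (0.127) calls were lost as well. With limma's fry the cholesterol (0.773), metallothionein (0.169) and ribosomal (0.261) calls were lost. The ribosomal call was also lost on arrays with the numerator in Cy3 (0.116), the cholesterol call with the mean over probes (0.0729) and the metallothionein call with ratios scaled between arrays (0.0543).

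DEX against VEH in Hes1 clone 1 and in clone 2 asked what the glucocorticoid changed in cells that overexpress Hes1. FOXO1, a transcription factor of metabolism and stress, rose by 2.88 in clone 1 (SD 0.023, n = 2, limma adjusted p = 5.3e-06) and by 2.89 in clone 2 (SD 0.21, adjusted p = 5.2e-06), with weakest probes at 1.44 and 1.67. The salivary proline-rich protein PRB1 rose by 2.67 (SD 0.17) and 2.98 (SD 0.020), and SLC19A2 rose by 2.32 (SD 0.42) and 2.21 (SD 0.089). TIPARP, an enzyme that adds ADP-ribose to proteins, rose by 1.64 (SD 0.41) and 2.28 (SD 0.16). AMIGO2 fell by 2.11 (SD 0.17, adjusted p = 4.9e-04) and 1.58 (SD 0.067, adjusted p = 0.002), and ARL14, a small GTPase, fell by 1.54 (SD 0.086) and 1.45 (SD 0.045). Without clone 2 replicate 1 the AMIGO2 call in clone 2 was lost (-1.53, adjusted p = 0.075).

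The rule named FAM90A1 (4.03) and SPINK13 (2.55) in clone 1 and PRB2 (2.60) and the fatty acid thioesterase OLAH (2.33) in clone 2 among the largest increases. Among the largest decreases were FGF5 (-1.42), the chemokine CCL2 (-1.41) and FHL2 (-1.32) in clone 1, and CNIH3 (-1.49), the cytokine GDF15 (-1.37) and IER3 (-1.35) in clone 2. PRB1 and PRB2 are close paralogs that share sequence, and another probe of FGF5 read -0.14. Leaving out replicate 1 or 2 ended the clone 1 calls for SPINK13 (1.87 or 3.24), FGF5 (-1.52 or -1.31) and CCL2 (-1.46 or -1.37), and the clone 2 call for CNIH3 (-1.31 or -1.67). The calls for SPINK13 (adjusted p = 0.0508) and CNIH3 (adjusted p = 0.0557) also ended, with the values themselves as before, without either replicate of clone 1 against control, and that for CNIH3 without either of DEX in clone 1 (adjusted p = 0.053). Leaving out replicate 1 ended the clone 2 call for GDF15 (-1.10). NR3C1 fell by 0.59 in clone 1 (adjusted p = 0.025) and 0.75 in clone 2 (adjusted p = 0.008), calls that were lost without replicate 1 (-0.68 and -0.88) or 2 (-0.50 and -0.62). HES1 read -0.55 in clone 1 (adjusted p = 0.39) and -0.28 in clone 2 (adjusted p = 0.999), which did not pass.

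Of the 36 glucocorticoid-induced genes, 22 rose, 0 fell and 14 did not pass in each clone (camera adjusted p = 2.3e-42 in clone 1 and 1.4e-47 in clone 2). In clone 1 26 rose and in clone 2 25 when adjusted over the list alone, and these calls held with an estimated correlation (adjusted p = 0.0057 with an estimated correlation in clone 1 and 0.0043 in clone 2). DUSP1 rose by 1.98 (SD 0.036) in clone 1 and 2.27 (SD 0.041) in clone 2, and FKBP5 rose by 1.07 in both (SD 0.066 and 0.045), with weakest probes at 0.66 and 0.72. BIRC3, an inhibitor of apoptosis, rose by 2.10 (SD 0.39) and 1.54 (SD 0.25), the clone 2 call being lost without replicate 1 (1.36). PDK4, a kinase that restrains glucose oxidation, rose by 1.94 and 1.82, with weakest probes at 0.52 and 0.40, and CEBPD, chosen after its values were seen as was RGS2, rose by 1.06 and 1.25. RGS2 rose by 1.04 and 0.98, calls that were lost without clone 1 replicate 1 (1.15) or 2 (0.94) and without clone 2 replicate 1 (0.84).

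Metallothioneins had a median of 1.11 in clone 1, where 2 of 12 rose and 10 did not pass, and 1.32 in clone 2, where 3 rose and 9 did not pass. Adjusted over the list alone 10 rose in clone 1 and 9 in clone 2, with 0 lower (camera adjusted p = 7.0e-11 and 1.2e-13, adjusted p = 0.415 and 0.417 with an estimated correlation). MT1M rose by 1.75 in clone 1 and 1.96 in clone 2, calls that were lost without clone 1 replicate 1 (1.53) and without clone 2 replicate 1 (1.93) or 2 (1.98). The probes of MT genes can read several members of the family. With limma's fry the list did not pass in either clone (0.088 and 0.0563). Heat shock genes were lower as a list in both clones (camera adjusted p = 1.1e-05 and 0.0022, adjusted p = 0.415 and 0.702 with an estimated correlation), with 1 of 15 past the threshold in each and 7 and 1 lower when adjusted over the list alone. That gene was DNAJB1, at -0.40 in clone 1 (adjusted p = 0.0026) and -0.50 in clone 2 (adjusted p = 0.0012), and the clone 1 call was lost without replicate 2 (-0.37). The clone 2 call of the list was lost on arrays with the numerator in Cy5 (0.064). With fry the heat shock list (0.111 and 0.313) and the inflammatory list below (0.197 and 0.104) did not pass in either clone. Of 33 inflammatory genes, 2 fell in clone 1 and 4 in clone 2, with 31 and 29 not past (camera adjusted p = 0.048 and 0.0022, adjusted p = 0.775 and 0.541 with an estimated correlation). Adjusted over the list alone 7 fell and 2 rose in clone 1, and 5 fell and 0 rose in clone 2, and without clone 2 replicate 1 the clone 2 call was lost (0.201). The clone 1 call of that list was lost without control replicate 1 (0.11) or 2 (0.107), clone 1 replicate 2 (0.217) and clone 2 replicate 1 (0.0522) or 2 (0.0518). It was also lost with median centring (0.128), scaled ratios (0.0865) or a replicate block (0.0531), on arrays with the numerator in Cy5 (0.168) and with only probes well above background on all 20 arrays (0.0755).

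In 4 further lists camera passed while 0 members did. Genes of G2 and mitosis pointed down in clone 1 (31 genes, camera adjusted p = 0.013, adjusted p = 0.813 with an estimated correlation, fry adjusted p = 0.72). That call was lost without clone 1 replicate 2 (0.229) and on arrays with the numerator in Cy5 (0.113). In clone 2 p53 targets pointed down (26 genes, camera adjusted p = 0.018, adjusted p = 0.714 with an estimated correlation, fry adjusted p = 0.494). The p53 call was lost without clone 2 replicate 2 (0.342) and with either dye order alone (0.141 and 0.0793). Ribosomal genes pointed up there (46 genes, camera adjusted p = 0.016, adjusted p = 0.702 with an estimated correlation, fry adjusted p = 0.441). This was lost without clone 2 replicate 2 (0.787), with either dye order alone (0.253 and 0.195), without saturated spots (0.841) and with the mean over probes (0.15). S phase genes also pointed up (30 genes, camera adjusted p = 0.013, adjusted p = 0.714 with an estimated correlation, fry adjusted p = 0.563). The call for S phase genes was lost without clone 2 replicate 1 (0.716), with median centring (0.48) and on arrays with the numerator in Cy3 (0.288). Adjusted over the list alone 4 p53 targets fell and 0 rose, and in the other 3 lists 0 passed.

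DEX changed 425 of 30520 genes in clone 1 (304 higher and 121 lower) and 387 of 30485 in clone 2 (287 higher and 100 lower), with 85 (71 higher and 14 lower) and 69 (56 and 13) of them by at least 2-fold. Without replicate 1 or 2 of the clone the counts were 97 and 159 in clone 1, of which 85.6% and 88.1% were higher, and 75 and 129 in clone 2. With ratios scaled between arrays 733 genes changed in clone 1, of which 60.8% were higher against 71.5%, and median centring in place of loess gave 189 in clone 1 and 194 in clone 2. With only the 4 arrays of each comparison fitted, the counts were 912 (53.9% higher) and 698. Both clones shared 200 higher and 60 lower genes, where 2.86 and 0.397 were expected from independent calls. Across genes the DEX ratios of both clones correlated with r = 0.80, where genes are not independent replicates.

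The difference in DEX response between the clones and control cells asked whether Hes1 overexpression went with another response. TAMALIN, a scaffold protein for glutamate receptors, responded less in the clones by -4.31 (SE 0.165, limma adjusted p = 7.1e-06), LPL by -3.77 (SE 0.275), ITGB2 by -3.58 (SE 0.0673, adjusted p = 1.3e-06), RGS2 by -3.55 (SE 0.129, or -2.38 with ratios scaled between arrays) and DLL1 by -3.43 (SE 0.289). In the clones LPL read -0.02 and 0.05, DLL1 0.02 and 0.10, and TAMALIN 0.39 and 0.25, none past the threshold. FHL2 fell less in the clones, by a difference of 2.92 (SE 0.138), or 1.84 with ratios scaled between arrays, and so did HMGA2, a chromatin protein (3.09, weakest probe 0.37), and PMEPA1 (2.85, SE 0.346). NR3C1 fell less as well (0.96, SE 0.112, adjusted p = 9.7e-04), or 0.48 with such scaling. HES1 fell less at its brightest probe (1.54, SE 0.244, adjusted p = 0.004, or 1.05 with such scaling). Its most 5′ probe read -1.51 in control cells, and -0.11 and -0.18 in the clones. At its middle probe, which was dim in control cells, the difference was 0.04. Under VEH the brightest HES1 probe was 18.1-fold higher in clone 1 and 8.40-fold higher in clone 2 than in control cells. Its DEX ratio in the clones therefore need not show the response of the cells' own HES1 gene.

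**Figure D1:**
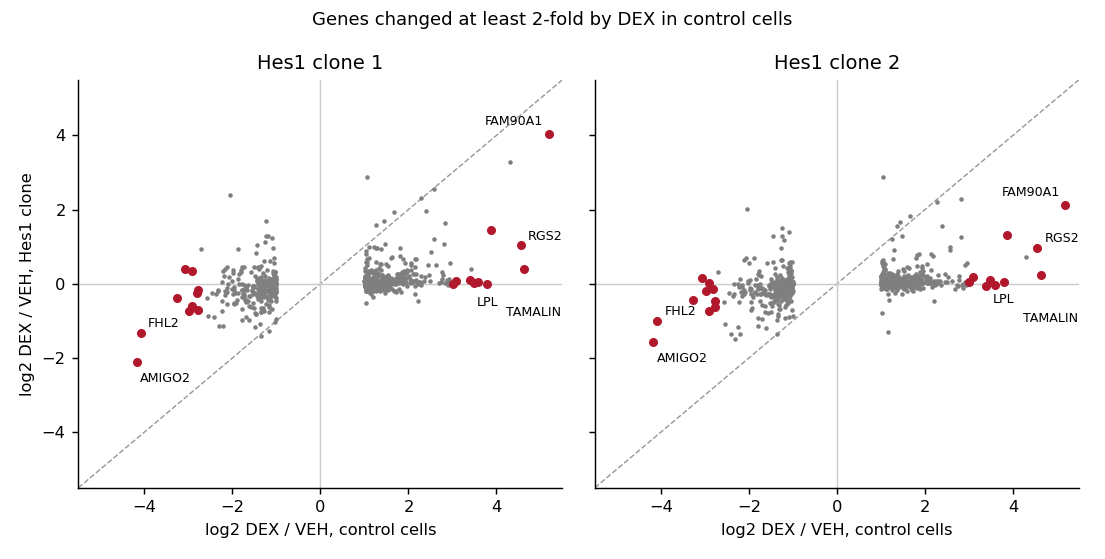
Log2 ratio of DEX over VEH in control cells (horizontal) against the ratio in Hes1 clone 1 (left) and clone 2 (right) for the 656 genes changed at least 2-fold in control cells; red points are the 20 genes named for control cells and the dashed line marks an equal response. In the direction of the control response, the estimate was smaller than in control cells for 649 genes in clone 1 and 651 in clone 2, genes of opposite sign included.

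Several genes differed in direction between control cells and the clones. CEBPB, a transcription factor of inflammation and metabolism, read -1.24 in control cells and 1.69 in clone 1 (difference for the mean of both clones 2.84, SE 0.0949, adjusted p = 4.2e-06), but its other probe gave a difference of 0.20 (adjusted p = 0.12). TGFBR2, a receptor of TGF-beta, read -1.44 in control cells and 1.04 and 1.29 in the clones (difference 2.61, SE 0.123, weakest probe 0.82). The glycosyltransferase GCNT1 read -1.25 against 1.29 and 1.30 (difference 2.54, SE 0.224), and SLC38A2, an amino acid transporter, -1.88 against 0.95 and 0.71 (difference 2.71, SE 0.135), though its weakest probe did not pass in the clones (0.53 and 0.47). The rule also named IRF2BP2 (3.35), LMCD1 (3.33) and FRMD6 (2.61) with positive differences, and KBTBD11 (-3.36), ATP4A (-2.99), ARC (-2.97), ZNF57 (-2.90) and SAG (-2.86) with negative ones. The weakest probes of IRF2BP2 and FRMD6 gave 1.87 and 0.77 (limma adjusted p = 9.6e-05 and 0.069). Leaving out clone replicates ended single-clone calls for TGFBR2 (0.90 without clone 1 replicate 1), GCNT1 (1.21 and 1.37 without clone 1 replicate 1 and 2, and 0.88 without clone 2 replicate 1) and SLC38A2 (0.78 without clone 1 replicate 1, and 0.51 and 0.90 without clone 2 replicate 1 and 2).

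Of the 372 genes that rose at least 2-fold in control cells, 357 (96.0%) had a lower DEX ratio in the mean of the clones. Another 1 had a higher one and 14 were not distinguished. The median of all 372 was 1.39 in control cells, 0.065 in clone 1 and 0.048 in clone 2. Of the 284 that fell at least 2-fold, 270 (95.1%) had a higher DEX ratio in the clones, 0 a lower one and 14 were not distinguished. Their medians were -1.32, -0.14 and -0.14. These counts include genes that changed the opposite way in the clones, such as GCNT1. The clone mean had the sign of control in 277 (74.5%) of the 372 and 193 (68.0%) of the 284. These genes were chosen on the control arrays, so the share of the response kept was also measured on genes chosen in 1 control replicate and read in the other. As a ratio of medians signed in the control direction, the clones kept 5.77% of the control response (SD 1.25 over 8 values, from 4.21% to 7.68%), with 6.13% in clone 1 and 5.40% in clone 2. Genes of opposite sign in the clones lower this ratio, so it is not the share that each gene kept. The 8 values share gene sets and control replicates, so their SD is a spread and not an error of the share.

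Glucocorticoid-induced genes differed from control in both directions. Of 36, 14 had a higher DEX ratio in the clones than in control cells, 6 a lower one and 16 were not distinguished (camera adjusted p = 0.015, adjusted p = 0.491 with an estimated correlation), and adjusted over the list alone 17 were higher and 7 lower. BIRC3 read -0.35 in control cells (adjusted p = 0.14) and differed by 2.17 (SE 0.183, adjusted p = 2.0e-04), DUSP1 by 1.74 (SE 0.108), DDIT4 by 1.64 (SE 0.0951), KLF9, a transcription factor, by 1.13 (SE 0.129) and FKBP5 by 0.78 (SE 0.0681, weakest probe 0.51). CEBPD responded less, by -1.65 (SE 0.0913), or -0.81 with ratios scaled between arrays. DUSP1, DDIT4, KLF9, FKBP5 and CEBPD were chosen here after their values were seen. Without control replicate 1 the list did not pass (camera adjusted p = 0.106), nor with only probes well above background in both channels on all 20 arrays (0.0769). Of 12 metallothioneins, 8 responded more in the clones, 0 less and 4 were not distinguished (camera adjusted p = 3.8e-06, adjusted p = 0.491 with an estimated correlation), 8 and 0 also when adjusted over the list alone. MT1M differed by 2.26 (SE 0.212) and MT1G by 2.40 (SE 0.341), and with saturated spots left out the list did not pass (0.076).

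**Figure D2:**
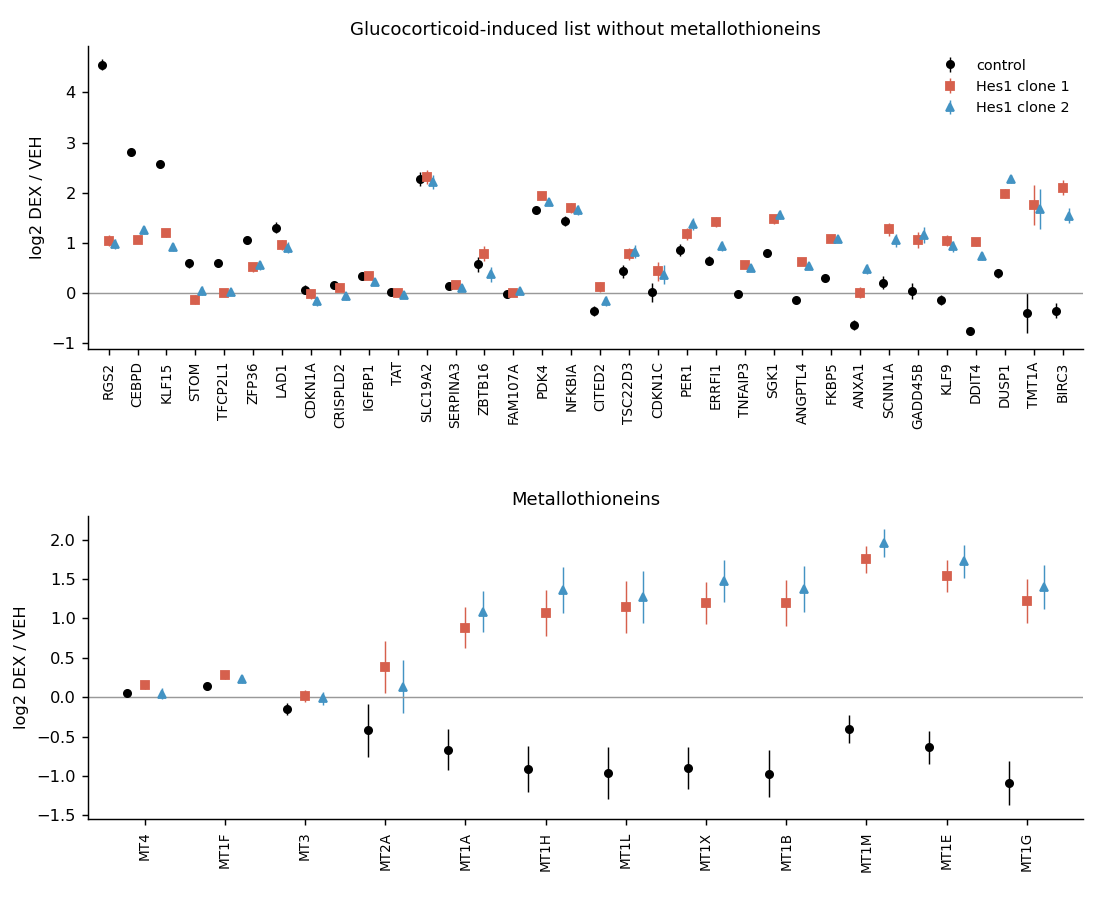
Log2 ratio of DEX over VEH in control cells (black circles), Hes1 clone 1 (red squares) and clone 2 (blue triangles) for 34 glucocorticoid-induced genes (top) and 12 metallothioneins (bottom), ordered by the clones minus control; error bars are the SE of the limma fit. In the top panel RGS2 lies toward the left (4.56 in control cells, 1.04 and 0.98 in the clones) and BIRC3 toward the right (-0.35, 2.10 and 1.54).

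Outside that list, FOXO1 responded more in the clones by 1.83 (SE 0.0798, adjusted p = 1.1e-05, weakest probe 1.17), PRB1 by 2.45 (SE 0.102) and OLAH by 1.64 (SE 0.0823). Heat shock genes fell less in the clones, with 8 of 15 differing, 0 the other way and 7 not distinguished (camera adjusted p = 3.8e-06, adjusted p = 0.491 with an estimated correlation), and 10 when adjusted over the list alone. DNAJB1 differed by 0.97 (SE 0.0472), or 0.58 with ratios scaled, and HSPA1A by 2.20 (SE 0.265), or 0.95 at its weakest probe, which did not pass. Of 31 genes of G2 and mitosis, 14 differed with a positive sign, 0 with a negative one and 17 did not (camera adjusted p = 4.4e-05, adjusted p = 0.491 with an estimated correlation), 16 when adjusted over the list alone, with UBE2C at 0.86 (SE 0.0773). Of 34 immediate early genes, 15 differed with a positive sign, 0 with a negative one and 19 did not (camera adjusted p = 9.0e-05, adjusted p = 0.491 with an estimated correlation), 16 and 1 when adjusted over the list alone, with KLF10 at 1.55 (SE 0.202) and EGR1 at 1.38 (SE 0.205). Of 37 genes of TGF-beta and Wnt signalling, 14 differed with a positive sign, 7 with a negative one and 16 did not (camera adjusted p = 0.015, adjusted p = 0.491 with an estimated correlation), 16 and 7 when adjusted over the list alone. Among these, ID1, an inhibitor of differentiation factors, differed by 2.34 (SE 0.187) and the matrix protein CCN1 by 2.10 (SE 0.146). Without control replicate 1 that list did not pass (0.0956).

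Of 24 genes of the receptor machinery, 10 had a positive difference, 3 a negative one and 11 were not distinguished, also when adjusted over the list alone (camera adjusted p = 0.0033, adjusted p = 0.491 with an estimated correlation). HSD11B2 differed by -1.55. The call for the list was lost without control replicate 2 (0.0538) and on arrays with the numerator in Cy3 (0.058). For 30 S phase genes 8 were positive, 0 negative and 22 not distinguished, or 12 and 0 when adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.743 with an estimated correlation, fry adjusted p = 0.133). The S phase call was lost without control replicate 2 (0.196) or clone 2 replicate 1 (0.1), with median centring (0.221) and on arrays with the numerator in Cy3 (0.058).

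The DEX response differed from control in 4342 genes for clone 1 (2285 with a positive difference and 2057 with a negative one) and in 4309 for clone 2 (2359 and 1950), and in 5534 for the mean of both (2958 and 2576). Without clone 1 replicate 1 or 2 the clone 1 count was 2096 or 2350, and without clone 2 replicate 1 or 2 the clone 2 count was 2112 or 2506. Without control replicate 2 the share with a positive difference was 42.4% for clone 1 against 52.6%, and 43.98% for clone 2 against 54.7%. Between clone 2 and clone 1 limma found 0 genes whose DEX response differed, with 553 at an unadjusted p under 0.05. Across genes the DEX ratios of control cells correlated with r = 0.22 with clone 1 and 0.18 with clone 2, where genes are not independent replicates.

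Of the 260 genes that changed the same way in both clones, 115 changed the same way in control cells, 63 the opposite way and 82 were not past the threshold there. Taken in the direction of the clones, the response of these 260 was larger in the clones for 164, smaller for 47 and not distinguished for 49. That split is tilted because the genes were chosen on the clones. Of genes that rose in control cells 102 also rose in clone 1 where 34.2 were expected from independent calls, and of genes that fell in control cells 79 rose in clone 1 where 38.3 were expected and 83 fell where 15.3 were expected.

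Each Hes1 clone against control cells, both under VEH, asked how the clones differed before treatment. HES1 was higher at its brightest probe, by 4.18 in clone 1 (SD 0.56, n = 2, limma adjusted p = 6.4e-05), which is 18.1-fold, and by 3.07 in clone 2 (SD 0.40, adjusted p = 3.0e-04), which is 8.40-fold. MAOA, which breaks down amine transmitters, was higher by 2.98 (SD 0.060) and 2.26 (SD 0.21), KYNU, an enzyme of tryptophan breakdown, by 1.86 (SD 0.093) and 2.55 (SD 0.040), and ANKRD1, a nuclear protein of stressed muscle, by 2.89 (SD 0.24) and 1.93 (SD 0.49). The chemokine CXCL14 was lower, at -4.31 (SD 0.30) and -4.54 (SD 0.72), as were TNNC1, the calcium-binding troponin, at -2.90 (SD 0.57) and -2.93 (SD 0.31), and the small heat shock protein CRYAB at -2.03 (SD 0.032) and -2.15 (SD 0.17). NR3C1 read 0.03 in clone 1 (adjusted p = 0.87) and -0.39 in clone 2 (adjusted p = 0.028), a call lost without clone 2 replicate 1 (-0.25, adjusted p = 0.353).

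The HES1 probes lie on chromosome 3 at 195338878 to 195338937 (most 3′ and brightest), 195336978 to 195337165 (middle) and 195336746 to 195336805 (most 5′), in a genome build that the files do not name. The middle probe was higher too, by 4.21 in clone 1 and 3.32 in clone 2. The most 5′ probe was lower, at -1.48 in clone 1 (SD 0.14, adjusted p = 1.2e-04) and -1.65 in clone 2 (SD 0.24, adjusted p = 2.2e-04). Under DEX that HES1 probe read -0.11 in clone 1 and -0.18 in clone 2, neither past the threshold.

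**Figure D3:**
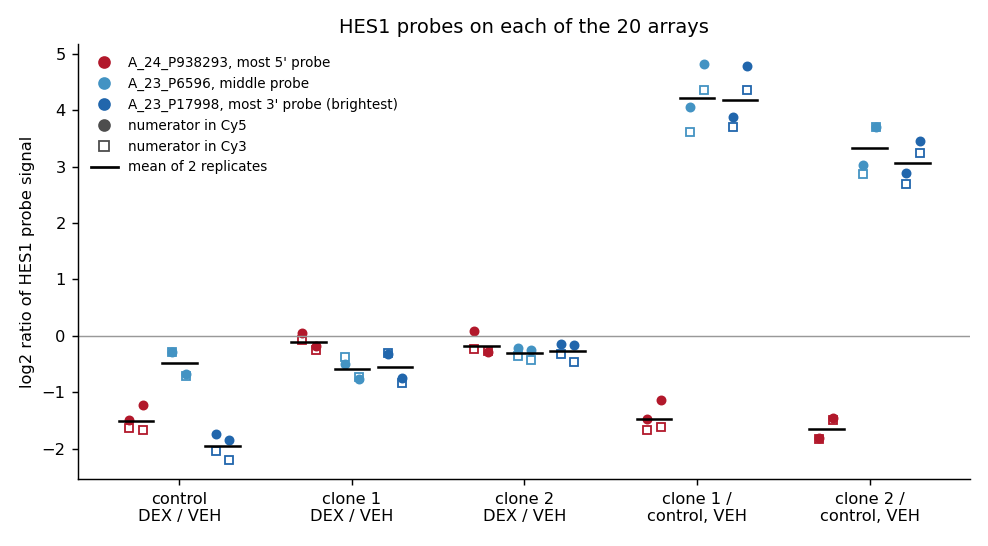
Log2 ratio of each of 3 HES1 probes (red most 5′, light blue middle, dark blue most 3′) on each of the 20 arrays, in the 5 comparisons; filled circles have the numerator in Cy5, open squares in Cy3, and bars are the mean of 2 replicates. Against control the most 3′ probe averaged 4.18 and 3.07 in clone 1 and clone 2, and the most 5′ probe -1.48 and -1.65.

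Taken as the mean of both clones, the rule also named KRT34 (2.53), CXCL8 (2.23), ARL14 (2.11), SLAMF7 (2.04), HK2 (2.04) and IL23A (2.03) among the largest increases. Among the largest decreases were ADGRG1 (-2.26), LOXL4 (-2.08), TTYH1 (-2.07), IGFBP5 (-2.06), IGF2 (-2.03), the keratin KRT17 (-1.81) and the protease HTRA1 (-2.44 in clone 1 and -1.57 in clone 2). Other probes of HK2, IGFBP5, TTYH1, LOXL4 and IGF2 read 0.13, -0.19, -0.45, -1.03 and -0.03. Leaving out replicates ended the call for CXCL8 in clone 1 (1.53 without replicate 2), and for IGFBP5 (-1.09) and KRT17 (-1.05) in clone 2 without replicate 1.

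**Figure D4:**
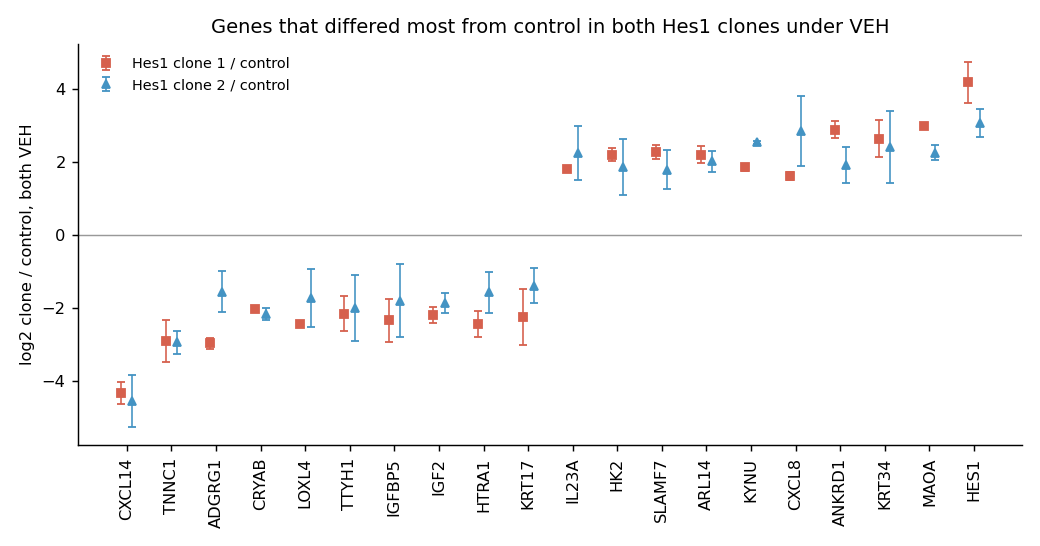
Log2 ratio of Hes1 clone 1 (red squares) and clone 2 (blue triangles) over control cells, both under VEH, for the 20 genes named by the rule; points are means and error bars the SD of 2 replicates. CXCL14 lies lowest at -4.31 and -4.54, and MAOA was higher by 2.98 and 2.26.

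Extracellular matrix genes were lower in clone 1, with 22 of 42 lower, 3 higher and 17 not past (camera adjusted p = 6.1e-06, adjusted p = 0.41 with an estimated correlation), and adjusted over the list alone 22 were lower and 4 higher. In clone 2, 12 were lower, 5 higher and 25 not past, 16 and 9 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.058). LOXL1, which crosslinks elastin, was lower at -1.93 and -1.53, and SPARC, a collagen-binding protein, at -1.39 and -1.36. The collagen COL5A1 averaged -1.30, its call being lost without replicate 1 in clone 1 (-0.83) and in clone 2 (-0.82). Of 31 genes of G2 and mitosis, 23 were higher in clone 1 and 8 did not pass, and in clone 2 8 were higher, 1 was lower and 22 did not pass (camera adjusted p = 3.3e-12 and 4.2e-04, adjusted p = 0.41 and 0.609 with an estimated correlation). In clone 1 25 were higher when adjusted over the list alone, and in clone 2 13 were higher and 1 lower. The mitotic kinase AURKA was higher by 0.78 and 0.48, and the checkpoint kinase BUB1 by 0.58 and 0.60, and without clone 2 replicate 1 both clone 2 calls were lost (0.30 and 0.49). With fry the G2 and mitosis list did not pass in clone 2 (0.118).

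Of 23 genes of the response to endoplasmic reticulum stress, 10 were higher, 2 lower and 11 not past in clone 1, and 8, 2 and 13 in clone 2 (camera adjusted p = 0.013 and 0.0013, adjusted p = 0.632 and 0.609 with an estimated correlation). The counts adjusted over the list alone were 11 higher and 3 lower in clone 1, and 9 and 3 in clone 2. The stress transcription factors ATF3 and DDIT3 were higher, by 1.60 and 0.86 and by 1.35 and 1.06, though the weakest probe of ATF3 did not pass in clone 2 (0.63). Without clone 1 replicate 2 the clone 1 list did not pass (0.056), nor did the clone 2 list with fry (0.0662). Of 37 genes of TGF-beta and Wnt signalling, 10 were lower, 4 higher and 23 not past in clone 1, and 7, 2 and 28 in clone 2 (camera adjusted p = 0.0077 and 0.0019, adjusted p = 0.41 and 0.609 with an estimated correlation). Adjusted over the list alone 10 were lower and 4 higher in clone 1, and 8 and 3 in clone 2, with the Wnt inhibitor DKK3 at -0.97 and -1.09 (weakest probe -0.45 and -0.63). Of 20 cholesterol genes, 7 were higher, 1 lower and 12 not past in clone 1, also when adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.677 with an estimated correlation), a call lost without replicate 1 (0.118), with HMGCS1, an early enzyme of sterol synthesis, at 1.47. Of 46 ribosomal genes 4 were higher, 1 lower and 41 not past in clone 2, or 2 and 0 when adjusted over the list alone (camera adjusted p = 0.033, adjusted p = 0.609 with an estimated correlation, fry adjusted p = 0.322). That call was also lost without clone 2 replicate 2 (0.124), with median centring (0.218), scaled ratios (0.0585) or the log ratios of the scanner software (0.0577), and with either dye order alone (0.207 and 0.0736).

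Genes known as direct targets of HES1 did not pass as a list in either clone (camera adjusted p = 0.16 and 0.22). Of 20, 6 were lower and 2 higher in clone 1, and 3 lower and 1 higher in clone 2, with 12 and 16 not past. Adjusted over the list alone the counts were the same, with HES1 itself among those higher. The list test was not run without HES1, the overexpressed gene, so it does not show how the other targets moved as a list. CDKN1B and CDKN1C, inhibitors of cyclin-dependent kinases that HES1 is known to repress, were lower, CDKN1B at -1.14 and -0.91 (weakest probe -0.33 and -0.25) and CDKN1C at -1.42 and -0.82, and without clone 2 replicate 1 both clone 2 calls were lost (-0.74 and -0.50), that of CDKN1C also within 1 scan date (adjusted p = 0.077). Of 38 genes of the Notch pathway, 8 were lower and 5 higher in clone 1, and 6 lower and 3 higher in clone 2, with 25 and 29 not past, and the list did not pass (camera adjusted p = 0.13 and 0.22). Counts adjusted over the list alone were 8 lower and 6 higher in clone 1, and 6 and 4 in clone 2. Of these, LFNG, which modifies Notch, was lower at -1.51 in clone 1 and -1.64 in clone 2, the latter call being lost without clone 2 replicate 1 (-1.21), and RBPJ, the DNA-binding factor of Notch signalling, at -1.16 and -1.07 (weakest probe -0.40 and -0.37, the latter not past the threshold). The glucocorticoid-induced list did not pass under VEH (camera adjusted p = 0.43 and 0.98), with 9 higher and 4 lower in clone 1, also when adjusted over the list alone, and 6 and 4 in clone 2, or 6 and 5 when adjusted over the list alone. In clone 2 that list's median (-0.02) and mean (-0.03) were negative while the test pointed up. Of 12 metallothioneins, 0 passed under VEH in either clone in limma.

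Clone 1 differed from control in 7328 of 30520 genes (4107 higher and 3221 lower) and clone 2 in 4243 (2017 higher and 2226 lower), with 364 and 152 of them by at least 2-fold. Of these 161 were higher and 203 lower in clone 1 (44.2% higher against 56.0% of all calls). In clone 2 50 were higher and 102 lower (32.9% against 47.5%). Both clones differed the same way in 2938 genes (1492 higher and 1446 lower), where 271.4 and 234.9 were expected from independent calls, and the opposite way in 138. Both comparisons share the control RNA. In 20 simulations with no clone effect that sharing gave r = 0.499 across genes, a covariance of 0.00313 and 66.7% of genes with the same sign. The observed values were r = 0.719, a covariance of 0.0457 and 70.1%. The simulations also gave 0 shared calls, but with no gene changed few calls arise in any case. They do not show how many of the 2938 shared calls come from the shared RNA. Fits within 1 scan date gave 4839 genes for clone 1, 1581 for clone 2 and 1145 for both. Without clone 1 replicate 1 or 2 the clone 1 count was 4083 or 4225, and without clone 2 replicate 1 the clone 2 count was 1262 and the shared count 950. With only its own 4 arrays fitted, clone 2 against control gave 0 genes in limma and HES1 read 3.07 with an adjusted p of 0.074, and with median centring the count was 1490, of which 32.9% were higher against 47.5%.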

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

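All tests of explanations in this part were chosen after the result was seen, except the baseline shift and the signal of the most 5′ HES1 probe over background.

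Most genes that responded to DEX at least 2-fold in control cells responded less, in the control direction, in both Hes1 clones. Over all genes and in either direction, the test of the difference passed in 4342 genes for clone 1, 4309 for clone 2 and 5534 for their mean. The largest positive differences were IRF2BP2 (3.35), LMCD1 (3.33), HMGA2 (3.09), FHL2 (2.92), PMEPA1 (2.85), CEBPB (2.84), SLC38A2 (2.71), TGFBR2 (2.61), FRMD6 (2.61) and GCNT1 (2.54). NR3C1 was at 0.96 and HES1 at 1.54 at its brightest probe, which need not read the cells' own gene in the clones. The largest negative ones were TAMALIN (-4.31), LPL (-3.77), ITGB2 (-3.58), RGS2 (-3.55), DLL1 (-3.43), KBTBD11 (-3.36), ATP4A (-2.99), ARC (-2.97), ZNF57 (-2.90) and SAG (-2.86). Compressed ratios on the clone arrays are argued against by 14 of 36 glucocorticoid-induced genes with a higher DEX ratio there. For the typical gene, clones already shifted under VEH are argued against by a median baseline shift of 4.51% of the missing response (2.80% to 7.72%). That median does not exclude such a shift in part of the genes. Of 3846 genes lower with DEX in control cells, 1384 were lower in the clones under VEH (523.2 expected from independent calls) and 824 higher (557.9). Of 3438 higher with DEX, 824 were higher (498.7) and 559 lower (467.7). Both comparisons have control VEH RNA as denominator, which can add to such overlaps. A further difference between the control DEX and control VEH cultures besides DEX cannot be told apart from the DEX response, because control DEX RNA was set only against control VEH RNA and replicates that correlate across genes (r = 0.866) would share it, and an effect of Hes1 overexpression, or of other differences of these clones from control, may account for the pattern but was not tested.

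Of 36 glucocorticoid-induced genes 14 had a higher DEX ratio in the clones than in control cells and 6 a lower one, and of 12 metallothioneins 8 and 0, list calls lost with an estimated correlation (adjusted p = 0.491 for both), for the first list also without control replicate 1 (0.106) or with only probes well above background on all 20 arrays (0.0769), and for metallothioneins without saturated spots (0.0764). Control DEX RNA exchanged for RNA of a clone is argued against by HES1, which fell in the control DEX RNA (-1.95), whereas both clones had more of it. Control cells in which these genes were already induced under VEH are argued against by a median shift of -0.0165 (SD 0.307) between clones and control under VEH for the 21 members that responded more, whose median difference in DEX response was 1.65. A weaker exposure of the control culture as the whole cause is argued against by 627 genes whose response, in the control direction, was larger in control cells. These are among the 656 chosen for a change of at least 2-fold on the same control arrays, which tilts the count. With genes chosen in 1 control replicate, the control median in the other replicate was 1.27 or 1.48, and the clone medians were 0.054 to 0.11. A further difference between the control cultures besides DEX stays open here too, and an effect of Hes1 on these genes may account for the pattern but was not tested.

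The HES1 probes moved in opposite directions between the clones and control, with the brightest higher and the most 5′ lower. A probe near background is argued against because the most 5′ probe was well above background in both channels on 8 of 8 arrays. A probe that reads another transcript which DEX does not lower is argued against by its fall with DEX in control cells (-1.51, on all 4 arrays). Another transcript that DEX lowers cannot be told apart, because 3846 genes were lower with DEX there and no value shows which transcript the probe reads. An introduced HES1 sequence that lacks the region of the most 5′ probe, together with less transcript from the gene of the cells, may account for opposite signs on 8 of 8 arrays, but it cannot be told apart from other causes, because the labels do not give the extent of the introduced sequence.

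In 45 tests, over several measures of the 4 arrays of each comparison, 1 array was set apart from the other 3 in 4. For independent tests chance gives about 1 in 20, but measures of the same arrays are related, so that rate is only a guide. In Cy3, 93.7% of spots were well above background on 1 array of DEX against VEH in control cells. In Cy5, 92.9% were well above background on 1 array of clone 1 against control. In Cy3, 20 spots were saturated on 1 array of clone 1 against control, and 73 on 1 array of clone 2 against control.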

How the results depend on the processing

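Fits within 1 scan date and array weights were chosen after the result was seen, and the other alternatives were planned. For named genes, apart from HES1 in each clone against control, alternatives other than leaving out a replicate counted 7962 values as kept. They ended a call in 352, added one in 55 and reversed 2, and for lists they kept 409 calls and ended 85. Here and with a replicate left out, a sign change of a value not past the threshold in the main fit counted as kept. Read from the weakest probe, a sign change counted as reversed only if both readings passed, and otherwise among the 352. Genes with a single probe counted as kept there. Leaving out a replicate kept 4234 values of named genes, ended 159 calls and added 14, and for lists kept 355 and ended 25. Where a cause is not named, the cause was not tested. Under the alternatives that gave a count of genes, the median log2 ratio of all genes lay within 0.0187 of 0. Normalisation within each array sets that median near 0, so it cannot show a shift of all genes. The share of the control response kept in the clones was 5.04% with genes of at least 0.58 on the log2 scale and 6.44% with genes of at least 2. Genes near background or saturated limit single values, such as RPLP1 and RPS2, saturated in both RNAs on all 4 arrays of every comparison.

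With an estimated correlation 0 of 8 lists passed for DEX in control cells, and with fry 9 did, 5 of the 8 among them. Of 38 list calls over all comparisons, 2 held with an estimated correlation, those of glucocorticoid-induced genes under DEX in each clone, and 21 held with fry. With median centring in place of loess DEX changed 3833 genes in control cells, 189 in clone 1 and 194 in clone 2. Clone 1 then differed from control in 4094 genes, clone 2 in 1490 and both in 987, and the DEX response differed in 1734 (clone 1), 1744 (clone 2), 2511 (their mean) and 1 (between clones). With ratios scaled between arrays DEX changed 733 genes in clone 1 and 638 in clone 2, the response of clone 2 differed from control in 2855 and between clones in 1, and the difference for TIPARP was 0.14 in place of -0.86. Read from its weakest probe, HES1 was -1.48 in clone 1, -1.65 in clone 2 and -1.56 in their mean against control.

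With all 20 arrays, a random block for dye pairs and a dye coefficient, counts were 1151 for DEX in clone 1, 986 in clone 2, 31 between clones and 4409 for both clones against control. Arrays with the numerator in Cy5 gave 757 for DEX in clone 1 and 2 between clones, and those in Cy3 gave 1 between clones. Fits on the arrays of each comparison alone left 1 residual degree of freedom and gave 3964, 912 and 698 genes for DEX in control, clone 1 and clone 2, 3785 for clone 1 against control, and 0 for clone 2 and for both, with HES1 at 3.07 in clone 2 (adjusted p = 0.074). At an adjusted p of 0.01, fewer genes passed by construction, 4516, 188 and 200 for DEX in control, clone 1 and clone 2, 4088, 1921 and 1282 for clone 1, clone 2 and both against control, and 2208, 2110 and 3048 for the response of clone 1, clone 2 and their mean against control. At 2-fold or more these counts were 656, 85 and 69, then 364, 152 and 94, then 681, 695 and 672.

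Within 1 scan date clone 1 differed from control in 4839 genes, clone 2 in 1581 and both in 1145, and array weights gave 850 for DEX in clone 1 and 1 between clones. With clone 1 from replicate 1 and clone 2 from replicate 2, both differed in 931 genes, and with the replicates the other way round in 2078. A block for replicates gave 7713, 487 and 414 genes for DEX in control, clone 1 and clone 2. Replicate deviations correlated between comparisons with r from -0.295 to 0.469 across genes. Comparisons with the same VEH RNA in their titles had the sign that sharing gives (0.301, 0.211 and 0.469 as common denominator, otherwise -0.295 and -0.164). Comparisons without a shared RNA ranged from -0.148 to 0.347. These values do not establish that replicates were paired, and the main fit took no account of shared RNA. A block for scan date was not run, since each comparison lies within a single date.

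Leaving out 1 replicate, where a lone replicate is assumed to vary like the others, gave 5059 to 7227 genes for DEX in control cells, 97 to 461 in clone 1 and 75 to 400 in clone 2. Against control it gave 4083 to 7721 for clone 1, 1262 to 4561 for clone 2 and 950 to 3157 for both. The DEX response differed from control in 2096 to 4325 genes for clone 1, 2112 to 4299 for clone 2, 4008 to 5598 for their mean, and 0 to 2 between clones. Between 4 and 10 lists passed for DEX in control cells, and HES1 against control ranged from 3.79 to 4.57 in clone 1 and from 2.79 to 3.35 in clone 2.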

Other observations

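The tests in this part were planned, and no explanation is weighed here.

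In control cells DEX also changed single genes of bone, low oxygen and the clock, while none of these lists passed camera there. VDR, the vitamin D receptor, rose by 2.77 (SD 0.050, n = 2, limma adjusted p = 1.2e-06), while 5 of 22 osteoblast genes fell and 2 rose, with 15 not past (camera adjusted p = 0.47), the same counts as when adjusted over the list alone. BMP2, a growth factor of bone, fell by 0.75. Of 19 genes induced by low oxygen, 4 rose, 1 fell and 14 did not pass (camera adjusted p = 0.42, fry adjusted p = 0.0062), the same when adjusted over the list alone, where 23.9% of all genes passed, with the vascular peptide ADM at 1.60 and NDRG1 at 2.14 (weakest probe 0.57). The repressors of the clock BHLHE41 and BHLHE40 fell by 2.10 and dropped by 1.53, among 20 clock genes of which 5 rose, 8 fell and 7 did not pass (camera adjusted p = 0.33). For the difference in DEX response between the clones and control the clock list passed, with 5 positive, 3 negative and 12 not distinguished, or 9 and 4 when adjusted over the list alone (camera adjusted p = 0.044, adjusted p = 0.644 with an estimated correlation), a call lost without control replicate 2 (0.103) or clone 2 replicate 1 (0.0694), on arrays with the numerator in Cy3 (0.104) and with the log ratios of the scanner software (0.0569). The response of VDR was smaller in the clones by -2.56 (SE 0.107).

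Notch and inflammatory genes went both ways in control cells. LFNG, which modifies Notch, fell by 2.57 and the corepressor TLE3 rose by 1.90 (weakest probe 1.26), among 38 Notch genes of which 4 rose, 9 fell and 25 did not pass (camera adjusted p = 0.25), the same when adjusted over the list alone. Of 33 inflammatory genes 2 rose, 9 fell and 22 did not pass (camera adjusted p = 0.094), the same when adjusted over the list alone, with the NF-kappaB subunit RELB at -1.42 (SD 0.032), the cytokine IL11 at -1.37 (SD 0.042) and PTX3, a pattern recognition protein, at 2.78 (SD 0.63). In the clones the ligand WNT5A rose by 1.71 in clone 1 and 1.93 in clone 2, calls that were lost without replicate 1 of the clone (1.61 and 1.92), and CCN2, a matrix protein of the TGF-beta response, rose by 1.47 and 1.21.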
